A study of Mus musculus with 12 samples.

How the data were processed

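The 12 libraries come from hematopoietic stem and progenitor cells of young and old wild-type mice, with 3 libraries each for BEU buffer and for CMC at each age. Per the labels' protocols, small RNA under 200 nt was purified, demethylated with wild-type AlkB and a mutant AlkB, incubated in BEU buffer with or without CMC, treated with sodium carbonate buffer, ligated to adaptors and copied with SuperScript III reverse transcriptase. The submitters' processing notes name Bowtie2 2.3.5, Bowtie and the mouse genome build mm10, without their roles. The rule that sets which read ends count as stops is not given in the sources used here.

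The authors deposited 6 tables, each with the BEU and the CMC library of 1 age and replicate number, and 28302 rows over 404 tRNA entries. Per the file headers, each row holds the coverage, a count of reads over the base, the number of stop reads and the stop rate. The deposited stop rate is a percent and equals 100 times stop reads over coverage in every row. The lowest value of both coverage and stop reads is 1. Among values with at least 5 stop reads and coverage under 2000, stop reads exceeded the step in coverage from the base before by 1 in 21.7%. They equalled that step in 11.0%, so a constant of 1 may have been added. The deposited values were used as they stand, and with 1 subtracted as an alternative. Coverage never exceeded 8015, a limit resembling a depth cap, and once a tRNA reaches it the stops 3′ of it are recorded as 1. A site was taken as below the ceiling when coverage at it or 5′ of it stayed under 7500 in all 12 libraries; this set was chosen after the ceiling was seen. The strongest stops lay on T in the deposited rows: 98.6% of the sites with a rise of at least 30 points in both ages, against 50.0% and 21.2% when moved by 1 base to either side, so no shift was applied. Stops were hardly recorded within 14 rows of the 3′ end. No entry is mitochondrial, so shares of mitochondrial tRNA were not computed.

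Entries of identical tRNA copies hold identical values. The 404 entries were reduced to 213 distinct tRNAs, of which 60 stand for 251 entries; all 404 entries were run as an alternative. Near-identical tRNAs that remain separate share reads in an unknown way. Bases were numbered by the usual tRNA scheme: from the 5′ end to position 16, from the anticodon for 26 to 44 and from the T loop for 49 on, which placed 372 and 381 of the 404 entries. Other bases are given by their count from the 5′ end of the entry. Names of the entries did not match the gene table used here, so positions are those within the tRNA and no genome coordinates are given.

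Sites needed coverage of at least 20 in all 12 libraries. CMC-dependent stops were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test on pairs of stop and read-through counts, with a coefficient per library and a log-odds coefficient for each of the 4 groups, equal library sizes and no dispersion trend. A site was called with a Benjamini-Hochberg adjusted p under 0.05, a mean rise of at least 10 percentage points and a rise in all 3 replicates. The adjustment was made separately for T and for the other bases. The age difference was the interaction in the same model, at T sites whose rise averaged over the 6 pairs was at least 10 points. BEU stops were compared at bases with a mean BEU stop rate of at least 5%. Position groups were compared by two-sided exact permutation of the 6 pair means (smallest p 0.1) and by fry in limma 3.58.1 on log2((stops + 0.5) / (reads - stops + 0.5)), adjusted over groups with at least 3 tested sites. Abundance used the highest coverage of each tRNA in the 6 BEU libraries with TMM and filterByExpr in edgeR, which removed no tRNA. Errors are SDs over 3 pairs or libraries; the SE of an age difference combines both groups. The tables give no molecular identifiers, so reads are not independent molecules and counting error alone understates the spread.

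The named sites were fixed by a rule before the data were examined: per age the 10 called sites with the largest rise (at most 1 per anticodon and position) and the best-covered called site of each position group; the 5 highest and 5 lowest age differences where fewer than 10 pass; the best-covered tested site of each amino acid at positions 54 and 55; and the 5 largest BEU differences and 10 largest abundance changes in each direction past the threshold. The text names all position 54 sites of that rule and a selection at position 55. The rule for BEU stops was also applied below the ceiling.

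The tests were checked on simulated stops drawn from the real coverage, with the ceiling imitated, and odds changed 2-fold or 4-fold at known sites. The spread between simulated libraries was set in advance, not fitted to these data, and was independent between libraries. The shares recovered may be too high where real libraries vary more. Alternatives were coverage minimums of 50, 10 and 1, limma on log odds and on differences of stop rates, thresholds of 30 and 5 points, centring on CMC efficiency, counts summed per anticodon, replicate blocks, each replicate pair left out, and DESeq2 1.42.0 for abundance.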

Results

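Pseudouridine in transfer RNA (tRNA) was mapped in hematopoietic stem and progenitor cells, the blood-forming cells of the bone marrow, from young and old wild-type mice. The series title names pseudouridine synthase 10 (PUS10), an enzyme known to act in the T loop of tRNA, as induced by aging, and the profiling compared pseudouridylation between the ages. Small RNA was demethylated with AlkB enzymes, then treated with CMC, a carbodiimide that stays attached to pseudouridine and halts reverse transcriptase, or with the BEU buffer without CMC. There were 4 groups (young and old, each with BEU and with CMC) of 3 libraries, 12 libraries in all. The stop rate was the percent of reads covering a base that ended there, and a stop that CMC raised marks a candidate pseudouridine. The deposited tables hold 404 tRNA entries, which carried 213 distinct sets of values after entries with identical values were counted together. The highest coverage of each tRNA, summed over the 213, ranged from 533736 to 1061426 reads in the BEU libraries and from 201980 to 767650 in the CMC libraries. Coverage never exceeded 8015 reads at any base, and the number of the 213 tRNAs that reached at least 7500 ranged from 21 to 103 per BEU library and from 0 to 56 per CMC library. At such tRNAs stops 3′ of the ceiling are not recorded, so the main counts are given beside those from sites that stayed below it in all 12 libraries. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

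In young cells, most of the T sites called as CMC-dependent lay in the T loop and the anticodon stem and loop. Of 165 T sites at position 55, where TRUB1 and PUS10 are known to act, 129 were called. At position 54, the neighbouring T-loop base, where PUS10 is also known to act, 37 of 149 were called. At positions 38 and 39, the known PUS3 sites, 77 of 93 were called, and at positions 27 and 28, the known PUS1 sites, 87 of 128. At position 13, a known PUS7 site, 17 of 25 were called. In the position 55 group the largest rise was 83.1 ± 1.47 percentage points (SD, n = 3) at tRNA-Leu-CAG-4-1. Position 54 of tRNA-Gln-TTG-5-1 rose by 77.9 ± 2.96 points and that of tRNA-Gln-CTG-1-1 by 73.4 ± 3.53 points (SD, n = 3 each). Counting at most 1 site per anticodon, the next largest rises at position 55 were 71.9 ± 5.28 points at tRNA-Gly-CCC-4-1, 69.9 ± 4.96 at tRNA-Ala-TGC-4-1, 69.8 ± 3.73 at tRNA-Cys-GCA-5-1 and 67.1 ± 4.19 at tRNA-Ala-AGC-2-1 (SD, n = 3 each). Position 54 of tRNA-Arg-ACG-3-1 rose by 68.1 ± 4.01 points, position 38 of tRNA-Ala-AGC-6-1 by 66.9 ± 0.888 and position 27 of tRNA-Trp-CCA-6-1 by 66.2 ± 1.09 (SD, n = 3 each). Among the best-covered called sites of each position group, position 13 of tRNA-Glu-CTC-1-1 rose by 47.6 ± 2.62 points and position 35 of tRNA-Tyr-GTA-2-1, another known PUS7 site, by 44.3 ± 5.40. Position 38 of tRNA-Pro-TGG-2-1 rose by 38.4 ± 2.94 points, position 32 of tRNA-His-GTG-2-1 by 31 ± 0.650 and its position 28 by 20.3 ± 2.94 (SD, n = 3 each). Position 50 of tRNA-Lys-CTT-3-1 rose by 16.7 ± 4.34 points and D-loop base 21 of tRNA-Leu-CAG-2-1, counted from its 5′ end, by 10.2 ± 2.40. The His sites at positions 28 and 32 and the Lys site at position 50 reached the ceiling in 6, 6 and 7 libraries, where later stops are recorded as 1, so their BEU rates of 0.0333%, 0.167% and 0.121% were hardly measured and the rise is close to the CMC rate alone. Position 54 of tRNA-Arg-ACG-3-1, position 13 of tRNA-Glu-CTC-1-1 and position 38 of tRNA-Pro-TGG-2-1 reached it in 4, 4 and 3 libraries. Position 55 of tRNA-Ala-TGC-4-1 and of tRNA-Cys-GCA-5-1 lay at or 3′ of it in at least 2 libraries each. None of the 86 T sites at positions 26, 34 and 36 was called. With counts summed per anticodon, 2 of 35 T sites there reached the 10-point average for the age test. Their mean rise was 23.8 ± 4.41 points in young and 24.5 ± 8.34 in old pairs (SD, n = 3 each). In all, 412 of 2189 T sites passed in young cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, a rise of at least 10 points and a rise in all 3 replicates. Below the coverage ceiling, 210 of 1179 T sites passed. None of the 165 T sites at positions 64 to 68 and the 13 at position 72 was called, but stops within 14 bases of the 3′ end are hardly recorded in these tables.

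In old cells the same regions carried the CMC-dependent stops. Calls were made at 137 of 165 T sites at position 55, 43 of 149 at position 54, 78 of 93 at positions 38 and 39, 82 of 128 at positions 27 and 28 and 18 of 25 at position 13. Position 55 of tRNA-Leu-CAG-4-1 again led, with a rise of 85.1 ± 2.18 points (SD, n = 3). Position 54 of tRNA-Gln-TTG-5-1 rose by 77 ± 2.86 points and that of tRNA-Gln-CTG-1-1 by 74.2 ± 3.50 (SD, n = 3 each). Position 55 rose by 73.1 ± 3.52 points in tRNA-Gly-CCC-4-1, 70.6 ± 2.70 in tRNA-Ala-TGC-4-1, 68.9 ± 3.60 in tRNA-Cys-GCA-5-1 and 68.3 ± 4.15 in tRNA-Glu-CTC-2-1 (SD, n = 3 each). Position 38 of tRNA-Ala-AGC-6-1 rose by 69.9 ± 2.27 points, position 54 of tRNA-Arg-ACG-3-1 by 68 ± 3.47 and position 27 of tRNA-Ile-AAT-3-1 by 66.1 ± 3.40 (SD, n = 3 each). Of the best-covered called sites, position 13 of tRNA-Glu-CTC-1-1 rose by 49.2 ± 3.04 points, position 38 of tRNA-Pro-TGG-2-1 by 39.7 ± 0.892 and position 32 of tRNA-His-GTG-2-1 by 36.3 ± 2.16 (SD, n = 3 each). Position 35 of tRNA-Glu-TTC-3-1 rose by 12 ± 3.28 points, position 50 of tRNA-Lys-CTT-3-1 by 17.3 ± 1.35, position 28 of tRNA-His-GTG-2-1 by 21.4 ± 1.85 and D-loop base 20 of tRNA-Glu-CTC-1-1, at the ceiling in 7 libraries, by 29.8 ± 1.40 (SD, n = 3 each). In all, 443 of 2189 T sites passed the same test in old cells, and 232 of 1179 below the coverage ceiling.

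The called sites of both ages overlapped in 393 T sites, with 19 called in young cells alone and 50 in old cells alone. Below the ceiling 201 overlapped, with 9 and 31 called in young and in old cells alone. Without young replicate 2 the imbalance reversed, with 43 sites called in young and 37 in old cells alone. At position 55, 127 sites were called in both ages, at positions 38 and 39 77, and at positions 27 and 28 80. A call in a single age was not taken as a difference, since the age effect itself was tested separately. The calls were largely restricted to T. In young cells 18.8% of T sites passed against 0.356% of 7870 sites at A, C and G (odds ratio 64.9, two-sided Fisher's exact test p = 3.56e-246). In old cells the shares were 20.2% and 0.635% (odds ratio 39.7, two-sided Fisher's exact test p = 4.94e-246). Below the ceiling the odds ratios were 32.5 in young and 22.0 in old cells, and at least 14 rows from the 3′ end they were 58.2 and 35.7. The adjustment was made separately over T sites and over the other bases. With fewer calls, the other bases faced a stricter unadjusted cutoff, so part of the difference in share may come from the adjustment. Of the 208 sites with a rise of at least 30 points in both ages, a count that uses no p-value, 205 were T. Sites of near-identical tRNAs share reads and are not independent, so these p-values are too small.

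**Figure D1:**
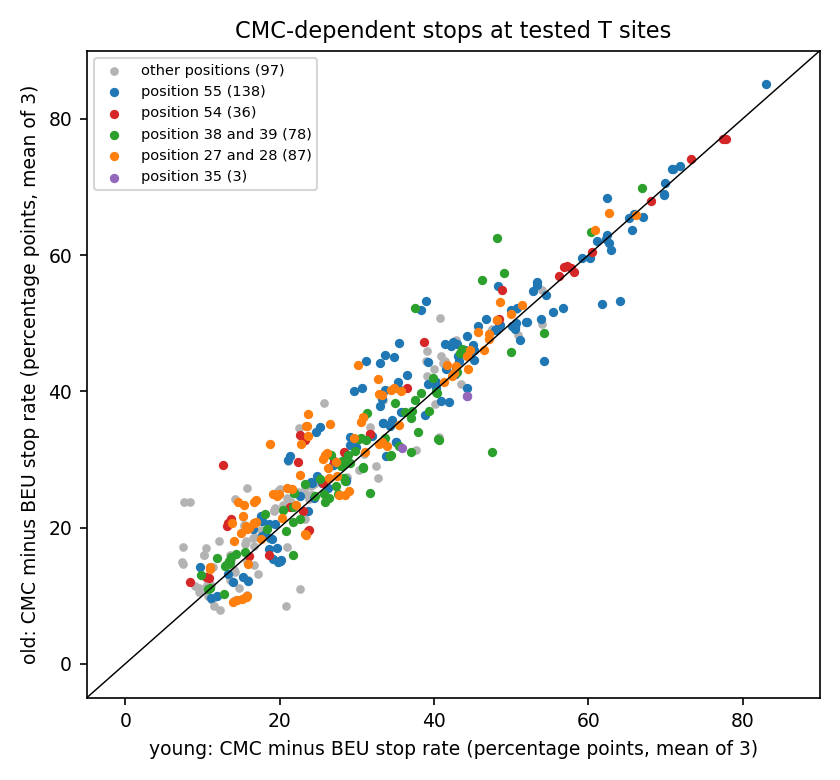
Rise in stop rate with CMC (percentage points, mean of 3 replicate pairs) in young cells (x axis) and old cells (y axis) at the 439 tested T sites, coloured by position in the tRNA, with the line of equal values. The sites lie along the line over the whole range, from around 10 points to 85.1 points at position 55 of tRNA-Leu-CAG-4-1.

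No single T site passed the test of an age difference in CMC-dependent stops. Over the 439 sites tested, the mean rise with CMC was 31.6 ± 3.24 points in young and 33.3 ± 2.23 in old pairs (SD, n = 3 each), a difference smaller than the spread (two-sided exact permutation p = 0.6, the smallest possible being 0.1). The median difference, old minus young, was 1.39 points, with quartiles of -0.927 and 3.88 points. The 5 highest differences, given as values, were at position 54 of tRNA-Leu-CAG-4-1 (16.4 ± 5.2 points, SE, n = 3 per age), D-loop base 21 of tRNA-Leu-CAA-4-1 (16.1 ± 4.01) and tRNA-Leu-CAA-2-1 (15.4 ± 4.24), and position 38 of tRNA-Ala-TGC-2-1 (14.7 ± 2.18) and tRNA-Ala-CGC-1-1 (14.4 ± 2.80). At position 38 of tRNA-Ala-CGC-1-1 the rise was 48.2 ± 1.16 points in young and 62.5 ± 4.72 in old cells (SD, n = 3 each), without overlap. The 5 lowest were at position 39 of tRNA-Ile-TAT-2-1 (-16.4 ± 3.13 points, SE), base 47 of tRNA-Phe-GAA-1-1 (-12.3 ± 8.03), position 50 of tRNA-Lys-CTT-2-1 (-11.7 ± 5.33) and position 55 of tRNA-Cys-GCA-18-1 (-10.9 ± 7.53) and tRNA-Arg-TCT-2-1 (-9.73 ± 6.66). Coverage at or 5′ of the Phe and Lys sites reached the ceiling in 4 and 5 libraries. The edgeR interaction test called 0 of 439 sites, with 21 at an unadjusted p under 0.05, and limma on log odds also called 0. Young and old pairs did not overlap at 57 sites (13%), where chance gives 10%. Below the ceiling 3 of 215 sites passed, all at position 35 of tRNA-Tyr-GTA, where tRNA-Tyr-GTA-2-1 and tRNA-Tyr-GTA-3-1 hold nearly the same values. In simulated data with a 2-fold change in odds the test recovered 0% of changed sites over all 439 and 51.4% below the ceiling, and with a 4-fold change 40.5% and 91.6%, so a 2-fold change was not detectable over all sites and was missed at many sites below the ceiling. Without old replicate 1 the test called 4 sites, all lower in old cells: base 47 of tRNA-Phe-GAA-1-1, base 48 of tRNA-Asn-GTT-3-1, position 50 of tRNA-Lys-CTT-2-1 and position 54 of tRNA-Arg-ACG-3-1.

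Grouped by position, no age difference was detected at the T-loop bases 54 and 55, though at position 54 alone the value was higher in old cells in every setting tried. Position 55 averaged 39.4 ± 7.21 points in young and 40.7 ± 2.73 in old pairs over 138 tested sites, and position 54 averaged 35.7 ± 3.62 and 38.5 ± 1.94 over 36 sites (SD, n = 3 each; two-sided exact permutation p = 0.9 and 0.4). The PUS3 positions 38 and 39 averaged 30.3 ± 1.17 and 30.6 ± 1.61 points over 78 sites, and the PUS1 positions 27 and 28 averaged 28.2 ± 0.832 and 31 ± 1.85 over 87 sites (SD, n = 3 each; exact permutation p = 0.8 and 0.2). Position 13 averaged 28.4 ± 2.88 and 31.2 ± 2.66 points over 17 sites (exact permutation p = 0.4). Position 35, at 3 tRNA-Tyr-GTA sites, was the group that passed limma's fry test of the log odds (adjusted p = 0.0174), and the test and the mean differed in sign. The log odds of a stop with CMC over BEU were higher in old cells, while the mean rise was 41.5 ± 4.49 points in young and 36.8 ± 3.37 in old pairs (SD, n = 3 each; exact permutation p = 0.2). At tRNA-Tyr-GTA-2-1 the stop rate without CMC was 5.31% ± 0.647 in young and 1.63% ± 0.466 in old cells, and with CMC 49.6% ± 4.83 and 40.9% ± 4.09 (SD, n = 3 each). Position 35 of tRNA-Tyr-GTA-4-1 and tRNA-Tyr-GTA-5-1 was called in young cells alone and missed the 10-point average for testing. The rises there were 12.4 ± 5.69 and 10.2 ± 4.72 points in young and 7.62 ± 3.37 and 5.33 ± 2.06 in old pairs. Their mean stop rates with and without CMC were also lower in old cells. That of tRNA-Glu-TTC-3-1, also untested, rose more in old pairs (6.73 ± 2.82 and 12 ± 3.28 points). For positions 54 and 55 together the adjusted fry p was 0.867, and it was at least 0.703 in the groups other than position 35. Below the ceiling the D-loop bases around position 20 also passed, at 13.8 ± 1.41 points in young and 17.6 ± 1.46 in old pairs over 10 sites (SD, n = 3 each; fry adjusted p = 0.00755, exact permutation p = 0.1), against an adjusted p of 0.703 over all 22. At 5 of these 10 sites, base 21 of tRNA-Leu-AAG-1-1, tRNA-Leu-AAG-2-1, tRNA-Leu-AAG-3-1, tRNA-Leu-TAG-1-1 and tRNA-Leu-TAG-2-1, the stop rate without CMC was itself called lower in old cells, and the mean rate with CMC was lower too. At tRNA-Leu-AAG-2-1 it was 12.3% ± 0.914 in young and 6.80% ± 0.452 in old cells without CMC, and 36.1% ± 4.65 and 31% ± 2.06 with CMC (SD, n = 3 each). The position 35 call ended without young replicate 2, young replicate 3 or old replicate 3 (fry adjusted p = 0.166, 0.0537 and 0.153). The tested sites then numbered 4, 3 and 5, so without young replicate 2 or old replicate 3 the set of sites changed as well. The 3 tRNAs of the main setting differ little in sequence. In young cells tRNA-Tyr-GTA-2-1 and tRNA-Tyr-GTA-3-1 both rose by 44.3 points, against 35.8 in tRNA-Tyr-GTA-1-1. With a mean coverage of 1146 reads in each, the first 2 are close to a single measurement. The difference at positions 54 and 55 together was 1.63 points, and -1.98 without young replicate 2, the pair with the most CMC-library tRNAs at the ceiling. The tested sites there rose from 174 to 184 without that pair, so the set of sites changed as well.

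**Figure D2:**
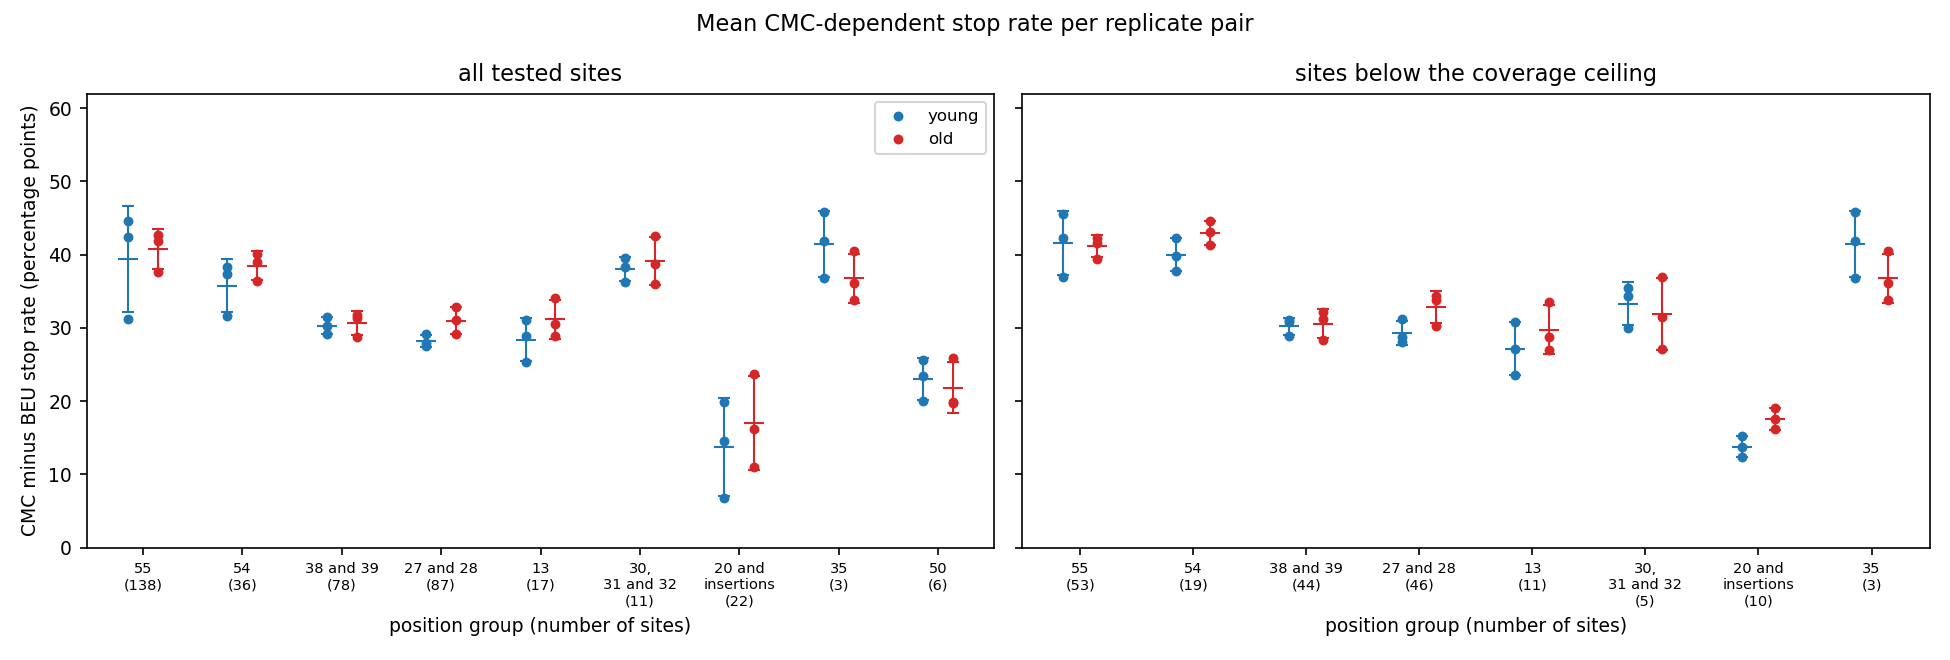
Mean rise in stop rate with CMC (percentage points, y axis) in each of the 3 young and 3 old replicate pairs for each position group (x axis, with the number of sites), over all tested sites and over sites below the coverage ceiling, with points for pairs and bars for the mean and SD. At position 55 the low young point is replicate 2, at 31.1 points over all tested sites and 36.9 points below the ceiling.

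By amino acid, CMC-dependent stops at position 54 were called in both ages at 6 of 6 Trp, 4 of 4 Pro and 8 of 9 Gln T54 sites, against 7 of 17 Arg and 3 of 13 Thr sites. Among the others, 3 of 13 Cys and 1 of 16 Leu sites reached the 10-point average for testing, and none of the 11 Ser, 10 Val, 5 Lys and 4 Tyr sites did. The differences between amino acids were not tested. The 6 tested Trp sites averaged 54.2 ± 0.677 points in young and 56.1 ± 1.49 in old pairs, and the 8 Gln sites averaged 48.0 ± 2.82 and 49.6 ± 3.10 (SD, n = 3 each). The 7 tested Arg sites averaged 37.8 ± 4.59 and 40.2 ± 2.56 points, and the 3 tested Thr sites 35.8 ± 3.73 and 37.9 ± 5.62 (SD, n = 3 each). The 4 Pro sites, all at the ceiling in 5 or 7 libraries, averaged 15.7 ± 12.1 and 23 ± 1.13 points (SD, n = 3 each). The best-covered position 54 sites rose in young and old cells by 38.7 ± 5.55 and 47.2 ± 2.71 points in tRNA-Trp-CCA-2-1, by 36.5 ± 2.19 and 40.5 ± 3.55 in tRNA-Gln-CTG-2-1 and by 48.2 ± 4.03 and 50.5 ± 5.64 in tRNA-Thr-TGT-3-1 (SD, n = 3 each). Those of Cys, Glu and Ile rose by 23.7 ± 4.82 and 19.5 ± 0.686 points (tRNA-Cys-GCA-2-1), 21.4 ± 3.23 and 23 ± 1.93 (tRNA-Glu-CTC-2-1), and 18.6 ± 4.30 and 16 ± 5.23 (tRNA-Ile-TAT-2-1). The sites with lower averages gave 13.2 ± 11.4 and 20.3 ± 0.834 points in tRNA-Pro-TGG-2-1, 10.5 ± 1.24 and 12.8 ± 0.642 in tRNA-Ala-TGC-4-1, and 8.41 ± 3.18 and 12.1 ± 2.85 in tRNA-Gly-CCC-4-1, which was called in old cells alone. In tRNA-Pro-TGG-2-1 young replicate 2 gave 0.0498 points; without it the young rise was 19.8 points, and with any other replicate left out the young call ended. The Gln, Thr, Cys and Ala sites reached the ceiling in 2 libraries each. At position 55 every amino acid other than initiator Met had tested sites. The averages there included 48.0 ± 5.86 points in young and 48.9 ± 1.34 in old pairs for 10 tested Ser sites, 47.8 ± 3.45 and 48.6 ± 0.870 for 16 Leu sites and 47.1 ± 7.03 and 48.9 ± 4.12 for 8 Gly sites, and the lowest in both ages were 22.4 ± 5.94 and 23.6 ± 2.99 for 2 Asp sites (SD, n = 3 each). Two-sided exact permutation tests of old against young gave adjusted p values of at least 0.928 for all amino acids at both positions, in a design whose smallest unadjusted p is 0.1. The best-covered position 55 sites of several amino acids lie at the ceiling: that of tRNA-Lys-CTT-3-1 reached it in 10 libraries and gave 35.5 ± 31.4 points in young and 47.1 ± 15.7 in old cells.

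Without CMC, stops mark other modifications, structure and RNA ends. They were lower in old cells at the first anticodon base of Arg-CCT and Thr-CGT tRNAs. At position 34 of tRNA-Arg-CCT-2-1 the BEU stop rate was 16.4% ± 1.33 in young and 8.04% ± 1.35 in old cells, and at position 34 of tRNA-Thr-CGT-2-1 8.11% ± 0.718 and 3.17% ± 0.580 (SD, n = 3 each; edgeR adjusted p = 0.0395 for both). These and the same base of tRNA-Arg-CCT-1-1 and tRNA-Arg-CCT-3-1 were the 4 sites past the threshold among 1190 tested. Below the ceiling, 49 of 893 sites passed, 47 of them lower and 2 higher in old cells. The lower ones included 10 of 25 tested sites at position 34, 7 of 21 at position 35 and 4 of 42 at position 26, where dimethylguanosine is common. Near-identical tRNAs share reads, as at position 34 of tRNA-Gln-TTG-1-1 and tRNA-Gln-TTG-3-1, so these sites are not independent. Position 34 of tRNA-Gln-TTG-1-1 fell from 28.7% ± 2.52 to 17.5% ± 0.299, that of tRNA-Ala-CGC-1-1 from 22.8% ± 1.07 to 14.7% ± 1.17 and position 26 of tRNA-Ser-GCT-5-1 from 26.4% ± 1.63 to 18.3% ± 0.800 (SD, n = 3 each; edgeR adjusted p = 0.00117, 0.00686 and 0.00819). Base 46 of tRNA-Arg-TCT-3-1 fell from 23.4% ± 3.23 to 15.6% ± 3.60 (adjusted p = 0.0291). The 2 higher sites were at position 16 of the D loop, in tRNA-Ala-CGC-2-1 (13.6% ± 1.46 in young and 20.1% ± 0.753 in old cells) and tRNA-Asn-GTT-3-1 (4.69% ± 0.945 and 9.04% ± 1.55; edgeR adjusted p = 0.0311 and 0.00434). With any replicate left out none of the 4 sites passed over all sites. Without old replicate 1 the test called 2 others, both higher in old cells. These were position 50 of tRNA-Lys-CTT-2-1, by 14.7 points, and base 47 of tRNA-Phe-GAA-1-1, by 20.7 points, and coverage at or 5′ of both reached the ceiling. Below the ceiling the test called 26, 30 and 24 sites without young replicate 1, young replicate 2 and old replicate 1. Limma on log odds called 0 sites in both sets, with 46 and 37 at an unadjusted p under 0.05.

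**Figure D3:**
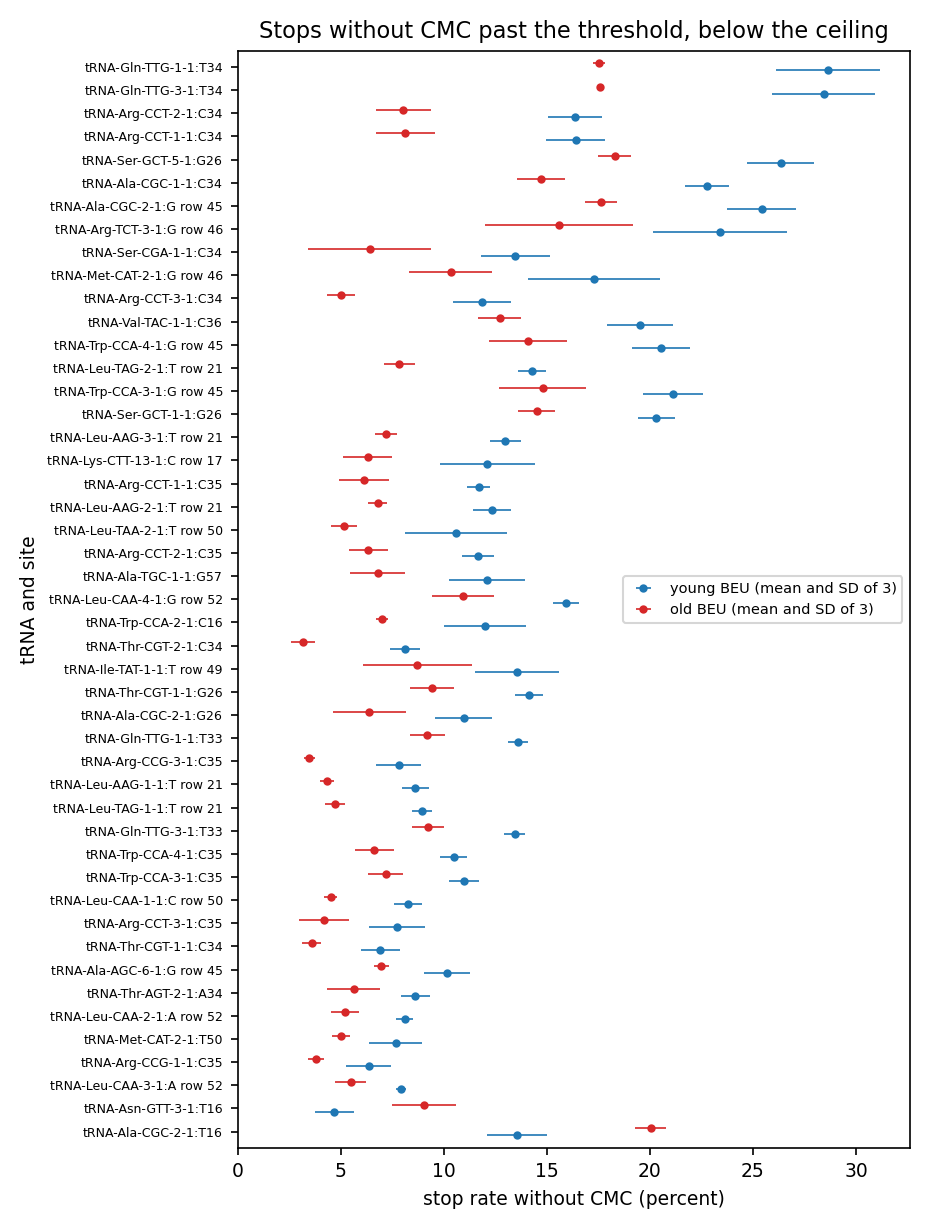
Stop rate without CMC (percent, x axis) at the sites below the coverage ceiling that passed the edgeR test (y axis), as mean and SD of 3 young and 3 old BEU libraries; position 37 of tRNA-Lys-TTT-1-1 and tRNA-Lys-TTT-2-1, at 92.9% and 93.6% in young and 88.4% and 89.9% in old cells, is left off the axis. The young values lie to the right of the old ones at every site drawn other than position 16 of tRNA-Ala-CGC-2-1 and tRNA-Asn-GTT-3-1.

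No tRNA passed the test of an age difference in abundance. Among the 110 tRNAs below the ceiling in the 6 BEU libraries, the median log2 fold change, old over young, was -0.01, and the values ranged from -0.76 in tRNA-Arg-TCT-4-1 to 0.63 in tRNA-Thr-AGT-7-1 (edgeR adjusted p = 0.375 and 0.197; both were chosen after their values were seen). The abundant tRNAs could not be compared: those of Gly-GCC, His-GTG-2-1 and Glu-CTC-1-1, among others, lay at the ceiling in all 6 libraries. Shares of each amino acid in the summed highest coverage, which is capped in this way, gave two-sided exact permutation p values of at least 0.1 and adjusted p values of at least 0.767. edgeR called 0 of 213 tRNAs, with 12 at an unadjusted p under 0.05, and 0 of the 110 below the ceiling in the 6 BEU libraries, with 19. DESeq2 called tRNA-Asp-GTC-2-1 alone (log2 fold change 0.69, adjusted p = 0.00809), which edgeR placed at 0.67 (adjusted p = 0.505). Adding the CMC libraries with treatment as a covariate gave 10 calls, 1 higher and 9 lower in old cells. Coverage at the ceiling compresses abundance: simulated 2-fold changes were recovered at 55% of changed tRNAs with the ceiling and at 87.5% without it.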

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

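The tests of position 35 with and without CMC, of the old CMC libraries at the lower BEU sites and of depth were chosen after the results were seen; the test by position was set before its result.

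Position 35 of tRNA-Tyr-GTA differed between the ages in the test of the age difference itself. Below the coverage ceiling the log2 odds ratio of CMC over BEU was higher in old than in young cells by 2.07 in tRNA-Tyr-GTA-1-1, by 1.41 in tRNA-Tyr-GTA-2-1 and by 1.41 in tRNA-Tyr-GTA-3-1 (edgeR adjusted p = 0.00570, 0.0340 and 0.0340), and over all sites the set of the same 3 had a fry adjusted p of 0.0174 (0.00755 below the ceiling). The CMC libraries alone went the other way, with log2 odds, old over young, of at most -0.38 against -2.06, -1.77 and -1.77 in the BEU libraries, which is consistent with a lower level without CMC in old cells rather than more CMC-dependent stops. Over all 215 sites tested below the ceiling, limma called 0 (13 at an unadjusted p under 0.05) and edgeR between 0 and 4 when a pair was left out, 0 without young replicate 2 or old replicate 3 and 1 without young replicate 3 or old replicate 1. For the set over all sites, the fry adjusted p was 0.0868 with the replicate number as a block. Below the ceiling the real split of the 6 pairs gave 3 sites and the highest other split 0 (1 of 10 splits was as large), too few splits for a share under 0.05. The 3 sites are not independent, since tRNA-Tyr-GTA-2-1 and tRNA-Tyr-GTA-3-1 hold nearly the same values. Over all sites the real split gave 1 position group past fry and the highest other split 4 (2 of 10 as large). Age and an unrecorded difference in handling stay open.

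The lower BEU stop rates in old cells form a wider pattern of 47 sites below the ceiling. A shift of the whole library would lower nearly all positions alike, yet the median log2 odds ratio was below 0 in 69.2% of 26 numbered positions. It was -0.46 for position 35 and -0.30 for position 34 against 0.05 for position 1 and 0.06 for position 16. The fall was not confined to the anticodon: each of the 26 that lies from position 33 to 59 had a median below 0, with -0.36 at position 56 and -0.27 at position 58. Of all 893 tested sites 544 were lower in old cells, with a median of -0.08. A library difference that reaches some regions more than others is therefore not opposed. Depth would move old BEU replicate 1, deeper than every young BEU library, against replicates 2 and 3, shallower than every young one, yet at the 23 sites called lower without replicate 1 it lay below every young library at 23, with a median fall 0.971 times that of the others. A fault of the BEU libraries alone would leave the CMC libraries unmoved, and of 35 lower sites other than T, 29 (82.9%) were lower in the old CMC libraries too. The share over all tested sites was not computed, and several of the 35 come from near-identical tRNAs that share reads. Such a fault is therefore not excluded. The split by age gave 47 sites and the highest other split 4 (1 of 10 splits was as large), again too few splits to give a share under 0.05, and limma called 0 sites. Age-linked RNA ends or modification, and a difference in handling of the BEU libraries alone or of both kinds of library, may account for the pattern.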

How the results depend on the processing

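The sites below the ceiling, the subtraction of 1, the 404 entries and the full-length reads were alternatives chosen after the data were seen. Coverage at the ceiling, the choice of test and single replicates set most of what changed; the cause was not tested unless the setting itself shows it. The numbers of called T sites in young and old cells were 149 and 164 with counts summed per anticodon, 210 and 232 below the ceiling, and 918 and 966 over all 404 entries, where fewer or more sites were tested, and 205 and 232 at the stricter threshold of 30 points. Below the ceiling they were 208 and 230 by limma and between 200 and 230 and between 220 and 247 with a replicate left out; other settings stayed within 1.5 times of 412 and 443. The overlap was 199 sites at 30 points, 149 summed per anticodon, 201 below the ceiling and 854 over all entries. The sites called in young and in old cells alone, 19 and 50, were 14 and 32 with a minimum of 50, 36 and 127 with a minimum of 1 read, 0 and 15 summed per anticodon, 9 and 31 below the ceiling, 64 and 112 over all entries, 6 and 33 at 30 points, 27 and 105 at 5 points, and between 13 and 43 and between 31 and 75 with a replicate left out (below the ceiling between 4 and 23 and between 21 and 45). The odds ratios of T against other bases were 117 and 73.6 with a minimum of 50, 271 and 186 at 30 points and 32.5 and 22.0 below the ceiling. The age difference in CMC-dependent stops had 3 sites below the ceiling and between 0 and 4 with a replicate left out, and 0 in all other settings; below the ceiling it had between 0 and 4 with a replicate left out and 0 by limma. The 4 BEU sites became 0 with a minimum of 10 or of 1 read, with limma, with 1 subtracted, with a mean rate of at least 20 percent and below the ceiling by limma, 1 with counts summed per anticodon, 49 below the ceiling in edgeR and between 0 and 2 with a replicate left out; the 49 became 0 by limma and between 24 and 52 with a replicate left out. The 2 BEU sites called over all sites without old replicate 1 were others, higher in old cells. Abundance gave 10 calls over all 12 libraries, 1 with DESeq2, 1 with full-length reads and 0 otherwise.

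Of the position groups, 1 passed fry in the main setting, 0 with a coverage minimum of 50, where no position 35 site was left, 0 summed per anticodon and 2 below the ceiling, and between 0 and 1 with a replicate left out. The position 35 difference stayed negative, at -5.46 points summed per anticodon (1 site, no set test) and between -7.28 and -2.55 with a replicate left out. The tested position 35 sites then numbered from 3 to 5, so this range also holds changes in the set of sites. The difference at positions 54 and 55 was -0.0234 points after subtracting the mean of all tested sites, and between -1.98 and 3.91 with a replicate left out. At position 55 alone it was -0.317 after that subtraction, -0.429 below the ceiling and between -2.78 and 4.01. At position 54 alone it stayed positive, at 2.75 in the main setting, 4.43 as a median and 1.83 with a coverage minimum of 50. It was 1.10 after the subtraction, 3.01 below the ceiling and between 0.497 and 3.98 with a replicate left out. At positions 38 and 39 it was -0.0828 as a median, -1.29 after the subtraction and between -0.241 and 1.28; at 30 to 32 -0.559, -1.41 below the ceiling and between -0.622 and 2.58; around 20 between -0.455 and 7.27 and at 50 between -3.19 and 0.177 with a replicate left out. Leaving a replicate out also changed the sets of tested sites, which numbered from 172 to 184 at positions 54 and 55 and from 17 to 30 around 20. Of all position groups, position 35 alone passed fry in the main setting.

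No pairing by replicate number was seen: the deviations of same-numbered CMC and BEU libraries correlated at -0.00288, -0.0521 and 0.0173 in young and -0.0143, 0.0914 and -0.0867 in old. Correlations near 0 with so few libraries per group cannot show whether same-numbered libraries share an RNA sample, which the labels leave open. As a replicate block, the replicate number left 0 BEU sites and 0 position groups (position 35 at -4.69 points, fry adjusted p = 0.0868) and gave 404 and 430 called T sites. The age difference in CMC-dependent stops and in abundance stayed at 0 calls. The block was not run below the ceiling. Of 1546 values of named sites and groups under alternatives, 1462 kept their direction and side, 66 lost a call, 6 gained one and 12 turned. Restriction to nuclear tRNAs moves nothing, since no other entries exist here, and no low-count filter removed a tRNA.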

Other observations

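The sites in the first 3 paragraphs were chosen after their values were seen, and the splits were planned. Outside the position groups fixed beforehand, 32 T sites were called in both ages. Position 40, next to the PUS3 positions, held 6 of them, and no other T site at position 40 was covered. The rise there was 54 ± 1.91 points in young and 49.9 ± 3.31 in old cells in tRNA-Ala-CGC-1-1, and 40.7 ± 4.59 and 50.7 ± 8.76 in tRNA-Arg-TCT-1-1 (SD, n = 3 each). Long variable arms of Leu and Ser tRNAs also carried such stops, among them base 47 of tRNA-Leu-CAA-1-1 with 47.4 ± 8.0 and 48.9 ± 3.47 points and base 46 of tRNA-Ser-GCT-3-1 with 28.7 ± 0.283 and 27.4 ± 4.14 (SD, n = 3 each).

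At A, C and G, 25 sites were called in both ages, and 12 of these lay next to a T called in young cells. The largest rise was at position 59 of tRNA-Tyr-GTA-5-1, at 53.6 ± 12.6 points in young and 60.3 ± 2.79 in old cells (SD, n = 3 each). Position 27 of tRNA-Val-CAC-1-1, a C, rose by 36.1 ± 11.6 and 44.6 ± 13.9 points, and position 37 of tRNA-Leu-CAG-4-1, a G, by 29.8 ± 7.29 and 42.8 ± 3.43 (SD, n = 3 each).

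Without CMC, single tRNAs had stop rates far above the median of their position. With the highest average over the 6 BEU libraries taken for each numbered position and base, the leading ones were 94.5% at position 37 of tRNA-Phe-GAA-2-1, 94.2% at position 55 of tRNA-Ser-GGA-1-1, 91.8% at position 37 of tRNA-Lys-TTT-2-1, 90.3% at position 26 of tRNA-Ile-AAT-3-1 and 87.6% at position 34 of tRNA-Leu-CAG-3-1. The median was 1.73% over 86 A sites and 1.37% over 52 G sites at position 37. At position 60, 6 of 123 T sites averaged at least 50%. At position 16 of the D loop, 21 of 54 T sites averaged at least 20%.

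The counts of the other splits of the same libraries were as follows; 10 splits cannot give a share under 0.05 in any of them. For CMC against BEU, with group means at least 10 points apart and no rule on single replicates, the real split gave 430 sites in young and 459 in old cells and the highest other split 0 in each (1 of 10 splits as large). For the age difference in CMC-dependent stops the real split gave 0 sites and the highest other 9, so 10 of 10 were as large; for BEU stops the values were 4 and 15 (2 of 10), for abundance 0 and 41 (10 of 10) and for position groups 1 and 4 (2 of 10). Each highest count came from the split that set young replicates 1 and 3 and old replicate 1 against the rest. Those pairs hold the 3 deepest BEU libraries, with summed highest coverage of 814489, 1032104 and 1061426 reads against at most 713459 in the others, which points to a structure of the libraries by depth. Below the ceiling the same split gave 0 CMC and 0 BEU sites. Yet at sites below the ceiling the BEU deviations of young replicate 3 correlated at 0.414 with old replicate 1, and at -0.262 and -0.229 with old replicates 2 and 3. For young replicate 2 the values in the same order were -0.315, 0.232 and 0.143, and for young replicate 1 -0.0885, 0.0197 and 0.0842. A structure by depth may therefore remain there.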
